A study of Homo sapiens with 6 samples.

How the data were processed

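RNA was measured in 6 libraries of SKM-1 cells: 2 untreated, 2 BOR, 1 VEM and 1 VEM+BOR. Groups were taken from the treatment labels. Replicate numbers follow accession order and pair no libraries. Per the labels' protocols, mRNA was purified with poly-T beads, primed with random hexamers and sequenced in 150 bp pairs on a NovaSeq instrument. The protocol names no strand-marking step, so reads of overlapping and antisense genes cannot be told apart. Per the submitters' processing notes the tools were CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.22.5, with no role given. The genome build is not given in the sources used here. Gene coordinates in the tables equal those of GENCODE release 29 (GRCh38) for 26698 of 26704 genes, and symbols for 26704.

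The authors deposited 3 tables, each setting 1 treated group against the untreated libraries. Each gives a normalised signal per gene and library, deposited as read counts divided by 1 factor per library. The deposited log2 fold changes and the deposited p-values and adjusted p-values are the authors' own. They were used only where the authors' deposited table is named. Every signal value was a whole multiple of its column's step within 0.001, so 100% of values came out whole and the reads were recovered. Recovered reads were 17371022 and 18031385 for untreated 1 and 2, 17694212 and 18507606 for BOR 1 and 2, 17252404 for VEM and 18337577 for VEM+BOR. The step of the VEM column is too near 1 for that recovery to be checked, so no count test used VEM. Each table holds genes with at least 2 reads over its libraries. Fewer reads give lower precision, and genes under a mean of 10 were left out. The 3 tables were scaled separately, and tests were made within a table unless stated.

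The plan, fixed before the data were examined, assumed raw counts and edgeR on all 6 libraries, with limma within 1 table if only normalised values were found. The latter applied. For VEM the plan also foresaw fold changes without a test if counts of all libraries could not be joined, so its p-values carry that limit. The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(value + 1), for genes with a mean value of at least 10, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. All tests were two-sided. The 1 VEM library and the 1 VEM+BOR library were assumed to vary like the untreated libraries. VEM+BOR against BOR and the departure from additive changes used 23519 genes found in all tables, brought to 1 scale by median-of-ratios factors, a step chosen after seeing the files. VEM+BOR against VEM was not tested.

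Gene lists, 31 in all, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of 1 comparison. An estimated correlation and fry were alternatives. Of the lists, 19 passed for BOR, 18 for VEM, 18 for VEM+BOR and 11 for VEM+BOR against BOR. With an estimated correlation or fry 0 passed in each. These alternatives rest on the residual degrees of freedom, 1 for VEM and VEM+BOR and 2 for BOR and VEM+BOR against BOR. With so few, only a very large statistic passes. Failing them therefore does not show that correlation between genes explains a list result. Named genes were protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between treated and untreated libraries, at most the 10 highest and 10 lowest changes, or 5 and 5 for the joint comparisons. CPM are reads scaled to the library total. Added to these were up to 4 members of each described list with the largest absolute change and a mean of at least 1 CPM, and a fixed set with BRAF, ARAF, YAP1, WWTR1, CDKN1A, CDKN2A and MKI67. Some genes that the rule takes in are not reported here. WWTR1 did not pass the filter on low values. Replicate libraries differed beyond sampling noise, with a chi-square per degree of freedom of 40.9 for the untreated pair and 262 for the BOR pair.

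The test was tried on simulated counts with the real means, library totals and a dispersion of 0.0932, taken from the untreated pair. The BOR pair spreads more widely, so the shares for designs with BOR libraries overstate what the test would find in these data. With 2 libraries against 2, for BOR over 15704 genes, it called 6.8% of genes raised 2-fold, 65.2% of those raised 4-fold and 100% of those raised 8-fold. For VEM over 15660 genes the shares were 2%, 43.6% and 96.4%, and for VEM+BOR over 15700 genes 3.6%, 55.2% and 93.6%. For VEM+BOR against BOR over 15711 genes they were 1.2%, 36.8% and 86.4%, and for the departure 0%, 3.6% and 24%. In the VEM+BOR design camera called 5 of 5 lists raised 2-fold and 1 of 150 random lists. The simulated genes varied independently, so these counts do not show how camera behaves when the members of a list vary together. Alternatives were edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, other filters, pseudocounts of 0.1 and 5, a test against a 1.5-fold change, TMM factors, scaling to the library total, all libraries in 1 fit and each replicate left out. Plots used matplotlib 3.10.9.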

Results

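SKM-1 is an established human acute myeloid leukaemia line that arose after a myelodysplastic syndrome. Poly-A selected RNA was sequenced from 6 libraries of these cells. The untreated group and the BOR group held 2 libraries each, and the VEM group and the VEM+BOR group held 1 library each. VEM is vemurafenib, a RAF kinase inhibitor, and BOR is a second compound whose abbreviation the labels do not spell out. Doses and times are not given in the sources used here. The series title names senescence and HIPPO signalling as the question behind vemurafenib treatment. Depth was similar, with 17252404 to 18507606 reads assigned to genes per library. Values below are size-factor normalised read counts, with mean ± SD for the untreated libraries (n = 2). Nothing in the labels says that the libraries of a group came from separate cultures. The p-values of single genes therefore rest on the spread between these libraries, which may be technical, and on the trend over genes. Camera p-values at the preset correlation set the genes of a list against the other genes. Their units are genes, not libraries, so they do not measure how a list would vary between libraries.

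VEM was compared with untreated cells to ask which transcripts differ after exposure to the RAF inhibitor. The genes past the threshold included 2 of the integrated stress response, the program run by the transcription factor ATF4. DDIT4, an inhibitor of mTORC1 signalling, was 1889 in VEM against 183.8 ± 32.6 in untreated cells, a log2 change of 3.37 (SE 0.41, adjusted p = 0.00209). CHAC1, which degrades glutathione, was 930.3 against 106 ± 3.85, a log2 change of 3.12 (SE 0.46, adjusted p = 0.00707). INHBE, an inhibin subunit gene, rose most, from 17.1 to 488.4, a log2 change of 4.76 (SE 0.65, adjusted p = 0.00518). The other increases past the threshold were PADI4, a peptidylarginine deiminase of granulocytes (log2 change 3.24), the immediate early transcription factor EGR1 (3.02) and the chemokine CCL5 (2.74). Their adjusted p-values lay between 0.00718 and 0.0101. The only decrease past the threshold was the long non-coding RNA UCA1 (ENSG00000214049), at 152.58 against 1461.7 and 886.73, a log2 change of -2.89 (adjusted p = 0.00546). UCA1 lies outside the rule for named genes and was chosen after its values were seen. Neither UCA1 nor PADI4 differed only in the libraries with VEM. With values brought to 1 scale, UCA1 was 256.7 in BOR 1 and 1337 in BOR 2, against 1343 and 806 in untreated cells. PADI4 was 568.2 in BOR 1 and 557.5 in BOR 2, against 247 and 87.08.

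These genes lie at the following places, in coordinates that equal those of GENCODE 29 on GRCh38. DDIT4 (ENSG00000168209) spans 72273920 to 72276036 on chromosome 10, and CHAC1 (ENSG00000128965) spans 40952962 to 40956519 on chromosome 15. INHBE (ENSG00000139269) spans 57452323 to 57459280 on chromosome 12, and EGR1 (ENSG00000120738) spans 138465490 to 138469315 on chromosome 5. PADI4 (ENSG00000159339) spans 17308195 to 17364004 on chromosome 1, and CCL5 (ENSG00000271503) spans 35871491 to 35880793 on chromosome 17. Each value sums reads over the annotated gene, so no exon or isoform is told apart.

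Among the 32 measured integrated stress response genes, 30 were above both untreated libraries in VEM, where chance places 33.3% of genes. Their median log2 change was 1.07. Over all genes tested 2 members passed, and 17 passed when adjusted over the list alone. ASNS, the asparagine synthetase gene, was 374.5 against 61.53 ± 8.73 (adjusted p = 0.208), and the cystine transporter gene SLC7A11 was 1436 against 425.5 ± 180 (adjusted p = 0.335). The list passed camera (adjusted p = 8.51e-43) and did not pass with an estimated correlation (adjusted p = 0.658).

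The NF-kB target list had a median log2 change of 0.46 in VEM (camera adjusted p = 1.37e-10, and adjusted p = 0.658 with an estimated correlation), with 23 of 30 members above both untreated libraries and 0 past the threshold over all genes, or 4 adjusted over the list alone. The list of senescence-associated secretory genes had a median of 0.53 (adjusted p = 8.55e-10, and adjusted p = 0.658 with an estimated correlation), with 19 of 26 members above both untreated libraries, 1 past the threshold and 3 adjusted over the list alone. Examples that did not pass alone were CXCL8 at 8343 against 2202 ± 1671, CCL3 at 623.2 against 146.6 ± 59.7 and CCL2 at 484.5 against 182.3 ± 149. Each of these chemokine genes belongs to both lists, so the lists are not separate observations. The prostaglandin synthase gene PTGS2 at 319 against 67.55 ± 3.83 and the survival gene BCL2A1 at 297.2 against 76.53 ± 23.9 did not pass either.

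Genes transcribed downstream of the MAPK pathway had a median log2 change of 0.30 in VEM (camera adjusted p = 8.24e-05, and adjusted p = 0.658 with an estimated correlation). Of 17 measured members, 12 were above both untreated libraries and 1, EGR1, passed the threshold over all genes and adjusted over the list alone. PHLDA1 was 80.25 against 25.76 ± 2.71, DUSP6 was 35.67 against 14.4 ± 8.23 and ETV5 was 2333 against 1455 ± 235, each with an adjusted p of 1. ARAF had a log2 change of -0.29 (SE 0.39). BRAF was 321 against 320 ± 9.97.

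The G2/M and mitosis list had a median log2 change of -0.19 (camera adjusted p = 4.96e-05, and adjusted p = 0.658 with an estimated correlation), with 19 of 30 members below both untreated libraries. None passed over all genes and 2 passed adjusted over the list alone. The G1/S and DNA replication list did not pass (median -0.07, camera adjusted p = 0.133). The proliferation marker MKI67 was 2126 against 6732 ± 1216 (log2 change -1.65, SE 0.40, adjusted p = 0.336), CENPF was 1108 against 3154 ± 1509 and CENPE was 478.5 against 1099 ± 452, both kinetochore genes. The list of cyclin-dependent kinase inhibitors had a median of 0.27 (camera adjusted p = 0.00191, and adjusted p = 0.658 with an estimated correlation), with 12 of 18 members above both untreated libraries and 0 past the threshold, also when adjusted over the list alone. CDKN1A, which encodes p21, was 1336 against 656.6 ± 382, CDKN2D was 341.8 against 167.1 ± 61.7, CDKN2C was 655.9 against 365.1 ± 79.7 and CDKN2A was 10610 against 6526 ± 531.

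The 33 measured HIPPO core components had a median log2 change of 0.19 (camera adjusted p = 0.0146) and the 19 measured YAP/TAZ-TEAD target genes a median of 0.29 (adjusted p = 0.0224), with 0 members past the threshold in either list, also when adjusted over the list alone. With an estimated correlation the adjusted p was 0.734 for the core components and 0.716 for the targets. Of the core components 18 were above both untreated libraries and 4 below, and of the targets 8 and 3, where chance gives 33.3% each. Against untreated 1 alone the medians were 0.08 and 0.08, and against untreated 2 alone they were 0.23 and 0.61. YAP1 was 224.9 in VEM and 158.7 ± 84.4 in untreated cells (log2 change 0.61, SE 0.54).

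Of the primary granule genes that mark myeloid progenitors, PRTN3 was 18830 against 54447 ± 5329, ELANE was 9891 against 27387 ± 10995 and MPO was 7041 against 18424 ± 2345, with log2 changes of -1.53, -1.41 and -1.38 and an adjusted p of 1 for each. CD38 was 293.3 against 141.6 ± 31.7. The monocyte and granulocyte list had a median of 0.47 (camera adjusted p = 0.015, and adjusted p = 0.716 with an estimated correlation), with 12 of 22 members above both untreated libraries, 0 past the threshold and 1 higher and 1 lower adjusted over the list alone. The list of stem and progenitor genes as a whole did not pass camera (median -0.26, adjusted p = 0.193), and 0 of its 21 members passed, over all genes or adjusted over the list alone.

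In limma, 7 of 15689 genes passed the threshold in VEM, and 399 had an unadjusted p under 0.05. VEM lay above both untreated libraries in 30.3% of genes and below both in 27.6%, where chance gives 33.3% each. The test had 1 residual degree of freedom, from the untreated pair, and assumed that the lone VEM library varies like that pair. The mean-variance trend over all tested genes added 18.0 degrees of freedom here and 19.7 for VEM+BOR. That trend therefore weighs more in these p-values than a gene's own spread. When all 6 libraries entered 1 fit, which takes in the wide spread of the BOR pair, 0 genes passed, and leaving either untreated library out of that fit also gave 0, while leaving out BOR 1 gave 17. The authors' deposited table gives 13 higher and 3 lower genes with an adjusted p under 0.05.

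VEM+BOR was compared with untreated cells to see the effect of both compounds together. PADI4 was 3620 against 183 ± 123, a log2 change of 4.48 (SE 0.49, adjusted p = 7.64e-05). The neutrophil chemokine CXCL8 was 21390 against 2206 ± 1670, a log2 change of 3.52 (SE 0.51, adjusted p = 0.00307). The myeloid kinase gene FGR (log2 change 3.32), the monocyte chemokine CCL2 (3.31), NLRP12 (3.14), the plasminogen activator inhibitor SERPINB2 (2.92) and the phagocyte oxidase subunit CYBB (2.83) also rose, as did LAMB3 (3.50), INHBE (4.28) and DDIT4 (2.85). The decreases were CYP1A1, a cytochrome P450 gene (log2 change -2.70, SE 0.53, adjusted p = 0.0356), the secreted glycoprotein gene CHI3L1 (-2.20, SE 0.43, adjusted p = 0.0338) and UCA1 at 42.322 against 1468.1 and 887.66 (-4.72, adjusted p = 7.72e-06).

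The monocyte and granulocyte list had a median log2 change of 0.91 in VEM+BOR (camera adjusted p = 7.52e-14, and adjusted p = 0.548 with an estimated correlation). Of 23 measured members, 17 were above both untreated libraries, 2 passed over all genes and 9 higher and 1 lower passed adjusted over the list alone. The calprotectin gene S100A8 rose from 1945 ± 487 to 7849 (adjusted p = 0.03), while TYROBP, a signalling adaptor of myeloid cells, was 146.7 against 19.96 ± 5.63 (adjusted p = 0.175) and the scavenger receptor gene CD36 was 38.38 against 8.039 ± 0.82 (adjusted p = 1). The progenitor granule genes did not pass, with MPO at 5136 against 18476 ± 2394 (adjusted p = 0.196), ELANE at 7695 against 27448 ± 10960 (adjusted p = 0.459) and PRTN3 at 17990 against 54588 ± 5216 (adjusted p = 1). CD38 was 377.9 against 142 ± 32.1 (adjusted p = 0.688). The stem and progenitor list did not pass camera (adjusted p = 0.355), its median of 0.14 and mean of -0.21 differed in sign, and adjusted over the list alone 2 members were higher and 2 lower, with 0 over all genes.

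The senescence-associated secretory list had a median log2 change of 1.19 in VEM+BOR (camera adjusted p = 5.9e-20, and adjusted p = 0.548 with an estimated correlation), with 5 of 27 members past the threshold over all genes, and 10 higher and 1 lower adjusted over the list alone. The NF-kB list had a median of 0.77 (adjusted p = 1.51e-19, and adjusted p = 0.548 with an estimated correlation), with 4 of 30 past the threshold and 7 adjusted over the list alone. PTGS2 rose from 67.73 ± 3.68 to 450.8 (adjusted p = 0.0302), and TNF was 82.68 against 5.591 ± 1.14 (adjusted p = 0.177). TNF, CXCL8 and CCL2 belong to both the secretory and the NF-kB list. The integrated stress response list had a median of 0.89 (adjusted p = 2e-33, and adjusted p = 0.548 with an estimated correlation). All 32 of its members were above both untreated libraries, 2 passed over all genes and 11 adjusted over the list alone. CHAC1 rose from 106.3 ± 4.11 to 665.3 (adjusted p = 0.019), SLC7A11 was 1489 (adjusted p = 0.0778) and ASNS was 194.9 (adjusted p = 0.751).

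MAPK output genes had a median log2 change of 0.56 in VEM+BOR (camera adjusted p = 1.76e-07, and adjusted p = 0.548 with an estimated correlation), with 13 of 17 members above both untreated libraries, 0 past the threshold and 2 adjusted over the list alone. PHLDA1 was 171.3 against 25.82 ± 2.66, EGR1 was 735.2 against 168.7 ± 72.9 (adjusted p = 0.0672), DUSP6 was 30.51 and ETV5 was 2623. The cyclin-dependent kinase inhibitor list had a median of 0.36 (camera adjusted p = 0.000204, and adjusted p = 0.567 with an estimated correlation), with 14 of 18 members above both untreated libraries and 0 past the threshold, also when adjusted over the list alone. CDKN1A was 1291 against 658.8 ± 385, CDKN2D was 341.5, ING1 was 975.4 and CDKN2C was 600.4. CDKN2A was 9363 against 6543 ± 517 and MKI67 was 3848 against 6752 ± 1235 (log2 change -0.80, SE 0.41, adjusted p = 1). The G2/M list had a median of -0.03 in VEM+BOR (camera adjusted p = 0.227, and adjusted p = 0.717 with an estimated correlation), with 7 of 30 members above both untreated libraries and 11 below. It had 0 members past the threshold, also when adjusted over the list alone. HIPPO core components had a median of 0.22 (camera adjusted p = 0.00657) and YAP/TAZ-TEAD targets a median of 0.22 (adjusted p = 0.0307), with 0 members past the threshold in either, also when adjusted over the list alone. Both had an adjusted p of 0.717 with an estimated correlation. With values brought to 1 scale, the core components differed by -0.19 and the targets by -0.34 between untreated 2 and untreated 1. Of the core components 19 of 33 were above both untreated libraries and 5 below, and of the targets 7 of 19 and 2, where chance gives 33.3% each. YAP1 was 229.3, and the log2 changes of BRAF and ARAF were 0.21 and -0.09.

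**Figure D1:**
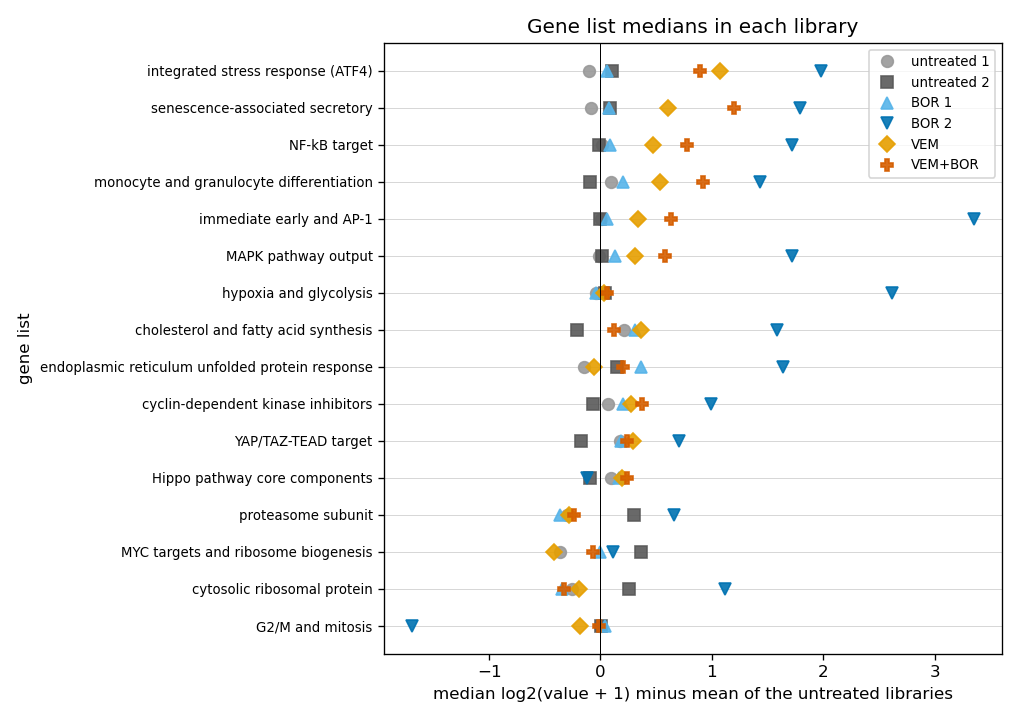
Median log2(value + 1) of each gene list in each of the 6 libraries, minus the mean of the untreated libraries, with values brought to 1 scale. Each point is 1 library. The integrated stress response list is high in VEM, VEM+BOR and BOR 2, and BOR 2 lies far from the other libraries in most lists.

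In limma, 30 of 15606 genes passed the threshold in VEM+BOR, 27 higher and 3 lower, with 469 at an unadjusted p under 0.05. With all 6 libraries in 1 fit 0 genes passed, also without either untreated library, while without BOR 1 that fit called 52, edgeR on recovered reads 90 and DESeq2 60. The authors' deposited table gives 48 higher and 12 lower.

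BOR was compared with untreated cells in 2 libraries against 2, and the BOR libraries differed from each other far beyond the spread of the untreated pair. BOR 1 lay close to untreated cells, and BOR 2 lay apart from all others. Across genes, which are not independent replicates, BOR 2 correlated at 0.86 to 0.88 with the other 5 libraries, which correlated at 0.964 to 0.985 among themselves. The untreated pair correlated at 0.968, less than untreated 1 did with BOR 1 (0.985), VEM (0.981) and VEM+BOR (0.973). Untreated 2 correlated with these libraries at 0.976, 0.964 and 0.970. The SD of the log2 difference from the untreated mean was 0.38 for BOR 1 and 1.46 for BOR 2. Mitochondrial transcripts made up 3.14% of reads in BOR 2 and 4.23% to 5.4% in the other libraries.

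Some genes of myeloid differentiation, sterol synthesis and the endoplasmic reticulum lay above untreated cells in both BOR libraries. TYROBP was 173.6 and 175 in the BOR libraries against 17.77 ± 4.96 in untreated cells, a log2 change of 3.25 (SE 0.61, unadjusted p = 0.0016, adjusted p = 0.968). TYROBP (ENSG00000011600) spans 35904401 to 35908295 on chromosome 19. LYZ, which encodes lysozyme, was 139.6 and 80.97 against 15.82 ± 8.92, and SERPINA1 was 1575 and 2506 against 667.9 ± 79.8. MNDA was 4627 and 300.4 against 3819 ± 595. The monocyte and granulocyte list passed camera (adjusted p = 2.99e-07, and adjusted p = 0.589 with an estimated correlation) with a median of 1.004, 0.17 in BOR 1 and 1.53 in BOR 2. Of its 22 members, 7 were above both untreated libraries in both BOR libraries, where chance gives 16.7%, and 1 passed adjusted over the list alone.

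Cholesterol and fatty acid synthesis genes had a median log2 change of 0.96 (camera adjusted p = 1.58e-14, and adjusted p = 0.589 with an estimated correlation), 0.31 in BOR 1 and 1.59 in BOR 2. Both BOR libraries lay above both untreated libraries in 22 of 31 members, where chance gives 16.7%. The list differed by -0.40 between untreated 2 and untreated 1. In VEM it had a median of 0.36 (camera adjusted p = 7.51e-06, and adjusted p = 0.742 with an estimated correlation), with 22 of 31 members above both untreated libraries, where chance gives 33.3%. INSIG1 was 1776 and 8614 against 994 ± 606, MSMO1 was 1409 and 5557 against 884.5 ± 260 and FADS2 was 5234 and 20590 against 3756 ± 2175, with 5294 in untreated 1. The unfolded protein response list had a median of 0.93 (camera adjusted p = 4.9e-09, and adjusted p = 0.589 with an estimated correlation), 0.37 in BOR 1 and 1.64 in BOR 2, with 14 of 25 members above both untreated libraries. HERPUD1 was 3132 and 16220 against 1779 ± 87.4, the chaperone gene DNAJB9 was 452.9 and 2561 against 312.1 ± 0.304, HYOU1 was 6062 and 24780 against 4611 ± 699 and XBP1 was 3147 and 11380 against 2532 ± 653. In both lists 0 members passed the threshold, also when adjusted over the list alone.

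In further lists that passed camera, BOR 1 had a median closer to untreated cells than BOR 2. Integrated stress response genes had a median log2 difference from untreated cells of 0.07 in BOR 1 and 1.99 in BOR 2 (camera adjusted p = 4.28e-12, and adjusted p = 0.589 with an estimated correlation). Hypoxia and glycolysis genes had a median log2 difference from untreated cells of -0.04 in BOR 1 and 2.62 in BOR 2. The glucose transporter gene SLC2A3 was 273 and 21630 against 270.2 ± 18.6, PFKFB4 was 192.4 and 28000, ANKRD37 was 65.34 and 2511, and ADM was 0.8951 and 3702 against 3.654 ± 1.56. Immediate early genes had medians of 0.06 and 3.36, with JUN at 655.2 and 44280, EGR1 at 108.3 and 15540, ATF3 at 48.33 and 6646 and FOSL2 at 83.24 and 1260. The G2/M list had medians of 0.04 and -1.69, with HMMR at 1401 and 32.65, TOP2A at 10420 and 279.5, CENPE at 1101 and 20.89 and CENPF at 2759 and 87.5. The camera adjusted p was 3.07e-14, 1.36e-13 and 3.51e-07 for these lists, and 0.589 for each with an estimated correlation. In these lists 0 members passed, also when adjusted over the list alone. MKI67 was 4013 and 703.9 against 6012 ± 1082, CDKN1A was 629.2 and 9150 against 586.3 ± 341, CDKN2A was 5415 and 13060 and YAP1 was 126.2 and 48.32. ARAF and BRAF had log2 changes of 0.52 and 0.28. Medians in BOR 1 and BOR 2 were 0.05 and 1.79 for senescence-associated secretory genes (camera adjusted p = 4.9e-09), 0.08 and 1.74 for NF-kB targets (1.18e-05) and 0.13 and 1.72 for MAPK output genes (7.43e-05). They were 0.19 and 1.10 for cyclin-dependent kinase inhibitors (0.00262) and 0.19 and 0.71 for YAP/TAZ-TEAD targets (0.0141), with adjusted p = 0.589 with an estimated correlation for these 5 lists. G1/S genes had medians of -0.03 and 0.97 (camera adjusted p = 0.00166, and adjusted p = 0.759 with an estimated correlation). HIPPO core components did not pass camera, with medians of 0.17 in BOR 1 and -0.12 in BOR 2 (camera adjusted p = 0.974, and adjusted p = 0.993 with an estimated correlation). In these 7 lists 0 members passed, also when adjusted over the list alone. Proteasome subunit genes had a median of -0.36 in BOR 1 and 0.66 in BOR 2, and heat shock genes 0.00128 and 0.17. With values brought to 1 scale, untreated 1 and 2 themselves lay at -0.30 and 0.30 for proteasome genes and at -0.17 and 0.17 for heat shock genes.

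In limma, 0 of 15382 genes passed the threshold for BOR, 38 had an unadjusted p under 0.05, edgeR on recovered reads called 0 and DESeq2 called 18. Both BOR libraries lay above both untreated libraries in 11.7% of genes and below both in 8.24%, where chance gives 16.7% each. Without BOR 1 the same test called 4008 genes, 1497 higher and 2511 lower, and without BOR 2 it called 0. With either BOR library left out, 1 library stands for BOR and only the untreated pair gives the spread. The authors' deposited table gives 18 higher and 0 lower. Scaling to library totals would shift BOR 2 by -0.60 on the log2 scale and move the median of all genes in this comparison from 0.04 to -0.26, and the medians of the proteasome list (0.15) and heat shock list (0.07) then turn to -0.15 and -0.23.

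VEM+BOR was set against BOR to ask what VEM adds. No table holds these libraries together, so values of the 3 tables were brought to 1 scale, and limma called 0 of 15438 genes, with 45 at an unadjusted p under 0.05. edgeR and DESeq2 also called 0. Hypoxia and glycolysis genes (median -1.30), cholesterol genes (-0.85) and ribosomal protein genes (-0.67) were lower and G2/M genes (0.94) higher by camera, and each had an adjusted p of 0.941 with an estimated correlation. Without BOR 2 the medians were 0.08, -0.26, 0.030 and -0.09 for hypoxia and glycolysis, cholesterol, ribosomal protein and G2/M genes. Without BOR 1 they were -2.76, -1.40, -1.39 and 1.96. Integrated stress response, NF-kB and senescence-associated secretory genes did not pass with both BOR libraries (medians -0.16, 0.23 and -0.23, camera adjusted p = 0.463, 0.463 and 0.981). Without BOR 2 their medians were 0.92, 0.58 and 0.90, and without BOR 1 they were -1.23, -0.77 and -0.94. Leaving out either BOR library sets 1 VEM+BOR library against 1 BOR library. Only the untreated pair then gives the spread, also behind the gene counts that follow. Without BOR 1 limma called 3648 genes, and without BOR 2 it called 0. CDKN1A had a log2 change of -1.04 (SE 1.52), MKI67 of 1.04 (SE 1.03) and YAP1 of 1.39 (SE 0.90). CDKN2A had 0.0043, ARAF -0.59 and BRAF -0.05. Against the untreated mean, YAP1 was at 0.65 in VEM+BOR, -0.06 in BOR 1 and -1.43 in BOR 2 on the log2 scale.

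A departure of VEM+BOR from the sum of the single log2 changes was tested in the same fit, and 0 genes passed, with 4 at an unadjusted p under 0.05. Without BOR 1 the count was 2022. In that fit each treated group was 1 library, and only the untreated pair gave the spread. With all libraries, MKI67 had a departure of 2.69 (SE 1.45), CDKN1A of -2.21 (SE 2.15), YAP1 of 0.77 (SE 1.27) and CDKN2A of -0.71 (SE 0.98). ARAF and BRAF had -0.31 and -0.07. MKI67, CDKN1A, YAP1 and CDKN2A differed from the untreated mean by -0.58, 0.23, -0.06 and -0.11 in BOR 1, on the log2 scale. In BOR 2 they differed by -3.08, 4.09, -1.43 and 1.16, so their departures depend on the BOR library used. Cholesterol genes had a median departure of -1.21 (camera adjusted p = 1.98e-16), integrated stress response genes of -1.18 (5.92e-11) and G2/M genes of 0.94 (8.05e-08), and each had an adjusted p of 0.704 with an estimated correlation. Without BOR 2 the medians were -0.62 for cholesterol genes, -0.20 for integrated stress response genes and 0.14 for G2/M genes. Without BOR 1 they were -1.72, -2.21 and 1.94.

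VEM+BOR and VEM were 1 library each. Their difference was planned as values without a test and was not tested, although the fit of all 6 libraries has residual spread to borrow. TYROBP was 134.9 in VEM+BOR and 15.46 in VEM, CLU was 1730 and 275.6, SERPINB2 was 1120 and 221.9, and ALOX5AP was 664.4 and 190.1, all on the common scale. CLU and ALOX5AP were chosen after their values were seen. The monocyte and granulocyte list had a median log2 difference of 0.51, with 19 of 23 members higher in VEM+BOR, and MYC target and ribosome biogenesis genes a median of 0.40, with 32 of 33 higher. The same lists differed by -0.19 and 0.73 between untreated 2 and untreated 1. Senescence-associated secretory, NF-kB and G2/M genes had medians of 0.33, 0.31 and 0.24. In these lists 19 of 27, 20 of 30 and 26 of 30 members were higher in VEM+BOR. Between untreated 2 and untreated 1 they differed by 0.17, -0.03 and 0.0022. Ribosomal protein genes (-0.13), cholesterol genes (-0.19) and integrated stress response genes (-0.11) differed less than between the untreated libraries, where the medians were 0.51, -0.42 and 0.21. The folds of MKI67, CDKN1A, CDKN2A, YAP1, BRAF and ARAF were 1.81, 0.969, 0.884, 1.02, 1.15 and 1.16.

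**Figure D2:**
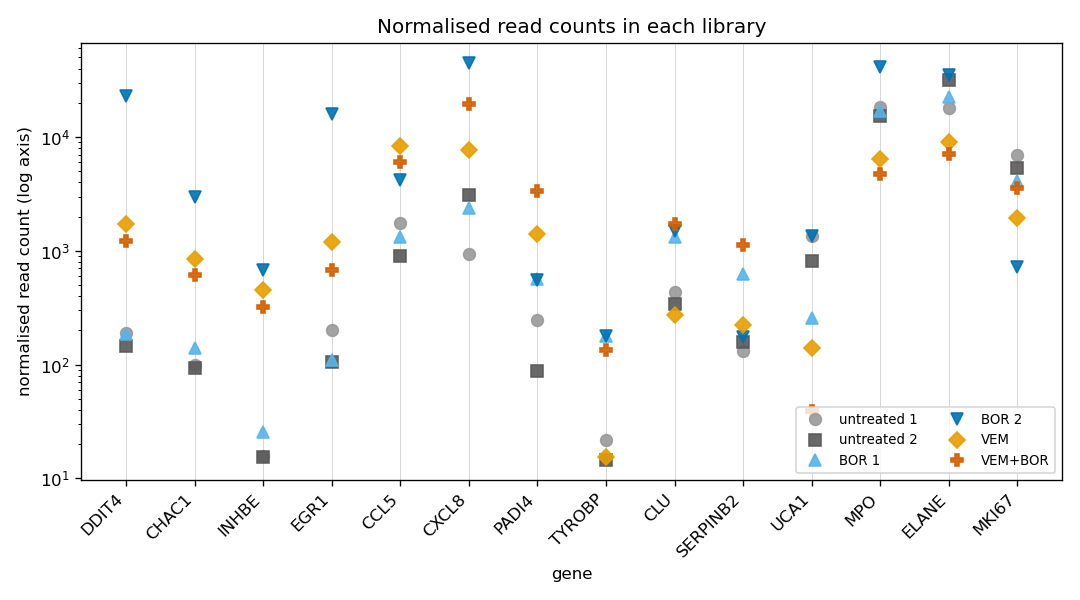
Normalised read counts on 1 scale, on a log axis, for 14 genes in each of the 6 libraries, 1 point per library. TYROBP and CLU are higher in BOR 1, BOR 2 and VEM+BOR than in the untreated and VEM libraries, and DDIT4 reaches 22980 in BOR 2.

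VEM and VEM+BOR shared 5 of their 6 and 27 increased genes and 1 of their 1 and 3 decreased genes, among 15439 genes tested in both. Independent lists of these sizes would share 0.0105 and 0.000194 genes, a value that leaves out the shared untreated libraries. Unchanged groups simulated against the same untreated libraries shared 0 calls in each of 100 simulations, but made on average only 0.04 and 0.03 higher and 0.1 and 0.08 lower calls, too few to share any. Part of the excess may come from the shared untreated libraries. The log2 changes correlated at 0.561 across genes with a covariance of 0.149. Unchanged groups set against the same untreated libraries gave a mean correlation of 0.333 and a mean covariance of 0.119 over 100 simulations, with a highest covariance of 0.127. The covariance exceeded the simulated mean by 0.0303. The simulations held the spread of the 1 untreated pair fixed, so their range understates the uncertainty. Measured against different untreated libraries the covariances were 0.0882 and -0.0235, which differ in sign. The excess therefore does not establish a shared effect.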

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

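Fits with TMM factors, library totals or all 6 libraries together in limma were chosen only after the result was seen. So were edgeR with TMM on recovered reads, and lists of VEM+BOR against BOR and the departure without 1 library. The plan itself had named edgeR with TMM on raw counts of all 6 libraries in 1 fit. No paired analysis was possible because replicate numbers only follow accession order. Pseudocounts of 0.1 and 5 left all counts of genes within 1.5 times. For VEM (7 genes), 0 passed without a filter, 2 against a 1.5-fold change, 40 with library totals and 0 with all 6 libraries. Leaving out 1 library from the fit of all 6 gave 0 to 17. For VEM+BOR (30 genes) the same settings gave 0, 7, 89 and 0, and 0 to 52 with 1 library left out. A mean of at least 5 CPM gave 56, TMM factors 51, edgeR 90 with either scaling and DESeq2 60. The 0 with all libraries goes with the BOR pair, whose spread enters that fit, since leaving out BOR 1 or BOR 2 gave 17 and 7 genes for VEM and 52 and 40 for VEM+BOR. The cause of the other shifts was not tested. For BOR (0 genes) DESeq2 gave 18, and leaving out 1 library gave 0 to 4008. The ranges were 0 to 3648 for VEM+BOR against BOR and 0 to 2022 for the departure. Gene lists past the threshold fell to 0 with an estimated correlation and with fry for BOR, VEM, VEM+BOR and VEM+BOR against BOR. Both alternatives rest on 1 or 2 residual degrees of freedom, so that fall cannot tell correlation between genes from a weak test. For BOR the lists past the threshold ranged from 7 to 20 with 1 library left out, 7 without BOR 2.

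Single genes changed sign with 1 library left out. For BOR the ranges of log2 change were -0.25 to 5.00 for ANKRD37, -0.13 to 1.18 for ARAF, -0.10 to 1.17 for CDKN2A, -5.42 to 0.23 for CENPE, -4.91 to 0.057 for CENPF, -0.40 to 6.75 for EGR1, -5.35 to 0.030 for HMMR, -3.66 to 0.29 for MNDA, -0.46 to 6.71 for PFKFB4 and -5.05 to 0.16 for TOP2A, the turn coming without BOR 2. For VEM+BOR against BOR they were -1.25 to 0.064 for ARAF, -0.14 to 0.029 for BRAF, -2.98 to 0.89 for CDKN1A, -0.63 to 0.64 for CDKN2A and -0.21 to 2.30 for MKI67. The departure ran from -0.97 to 0.35 for ARAF and -0.15 to 0.018 for BRAF. Against untreated cells ARAF ran from -0.27 to 0.13 in VEM+BOR and BRAF from -0.028 to 0.051 in VEM. With library totals BRAF turned to -0.020 for BOR, 0.15 for the departure and 0.21 for VEM+BOR against BOR, where edgeR gave 0.0048 and TMM factors 0.019. CDKN2A in that comparison turned to -0.12 with DESeq2, -0.051 with edgeR and -0.13 with RLE factors. Among other settings 936 values of the single genes reported kept their status, 61 lost a call and 37 gained one with the same sign. With 1 library left out the numbers were 334, 42 and 40. Values that kept their status include genes called in neither fit, so these counts do not show that the calls were stable. edgeR, DESeq2 and RLE factors were not run for VEM or the departure, and a fit of the compared libraries alone is already the main one within a table. Depth limits genes under a mean value of 10.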

Other observations

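The tests of other cell types, a label swap, shared untreated libraries, handling, the untreated pair and the recurrence of BOR changes were chosen only after the result was seen, and those of GC content with length and of the splits were not.

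Lists not described above also differed between libraries. Replication-dependent histone genes, whose transcripts mostly lack poly-A tails, had a median log2 change of -1.06 in VEM+BOR (camera adjusted p = 1.02e-05, and adjusted p = 0.717 with an estimated correlation), with 7 of 9 measured members below both untreated libraries. They differed by -1.08 between untreated 2 and untreated 1. Ribosomal protein genes had a median of -0.34 there (camera adjusted p = 1.02e-05, and adjusted p = 0.84 with an estimated correlation), with 42 of 56 members below both, but differed by 0.52 between the untreated libraries. All 13 mitochondrially encoded genes were below both untreated libraries in VEM+BOR (median -0.36, camera adjusted p = 0.0307, and adjusted p = 0.717 with an estimated correlation). In VEM 11 were (median -0.40, camera adjusted p = 0.0233, and adjusted p = 0.734 with an estimated correlation), where chance gives 33.3%. In BOR 9 were below in both libraries (median -0.35, camera adjusted p = 0.0161, and adjusted p = 0.589 with an estimated correlation), where chance gives 16.7%. The 7 measured stromal and epithelial markers had a median of -0.93 in VEM+BOR (camera adjusted p = 0.0178, and adjusted p = 0.804 with an estimated correlation), with 3 below both untreated libraries, but differed by -1.31 between the untreated libraries.

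CLU and TYROBP were high in all 3 libraries with BOR. CLU, which encodes the chaperone clusterin, was 1324 in BOR 1, 1507 in BOR 2 and 1730 in VEM+BOR, against 435.3 and 340.6 in untreated cells and 275.6 in VEM (log2 difference 2.13, SE 0.29, unadjusted p = 0.000363, limma adjusted p = 0.925). TYROBP was 177.2, 178.7 and 134.9 against 21.9, 14.51 and 15.46. With BOR and VEM as 2 terms limma called 0 of 15438 genes, 134 had an unadjusted p under 0.05, and the 3 libraries lay above the other 3 in 4.31% of genes, where chance gives 5%. The 10 splits of the 6 libraries are too few for a share under 0.05, and the highest other split called 7577 genes. That split sets BOR 2 with VEM and VEM+BOR, so beside the VEM term it isolates BOR 2, a structure of the libraries. A BOR effect on these genes is a hypothesis. Across genes, the changes of BOR 1 correlated at 0.228 with the difference of VEM+BOR and VEM, below the 0.337 for the difference of the untreated libraries, and those of BOR 2 at -0.00838. These values do not show a common BOR effect across genes, which stays open.

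BOR 2 stood apart from the other 5 libraries. A trend on GC content and transcript length is not the whole cause, since after its removal the SD of the log2 difference was 1.25, from 1.46, against at most 0.53 for the other treated libraries. The trend removed 26% of the variance, and genes under 42.3% GC had a median of -1.29, so a partial effect of RNA or library quality may be present. Marker genes of erythroid, lymphoid and stromal cells took 0.0249% of reads in BOR 2 and 0.019% to 0.0412% in the others. This share was not raised in BOR 2, but it holds genes that the other libraries express too. CD4 was 2046 in BOR 2 and 1242 to 1776 in the other libraries of its table, and COL6A2 was 1305 and 692.3 to 1627. The lymphoid markers had a median log2 difference from untreated cells of 0.45 in BOR 2 and -0.23 to 0.23 in the others. The erythroid (-0.41) and stromal (0.29) medians were not highest in BOR 2. RNA from other cells stays open. BOR 2 correlated at most at 0.878 with an untreated library, against 0.964 or more between the other 5 libraries. This restates that BOR 2 stood apart, and an untreated library with a quality effect could give it too. It therefore cannot decide on a label swap. A different dose, time or culture state of BOR 2 stays open and untested.

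VEM and VEM+BOR moved together against untreated cells. Measured against different untreated libraries the covariance of their changes was 0.0882 in one assignment and -0.0235 in the other, so shared untreated libraries cannot be told apart from a shared effect across all genes. The integrated stress response genes differed by 0.21 between the untreated libraries, less than the 0.96 or more by which VEM exceeded either. A stress of culture or handling common to these libraries cannot be told apart from the compounds, since no further library was handled with them by label. On the common scale the median of the integrated stress response genes was also 1.98 in BOR 2, which had no VEM by label, and 0.06 in BOR 1. A response to VEM in these genes is a hypothesis.

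MYC target, ribosome biogenesis and proteasome genes passed camera as lower in VEM, with medians of -0.43 and -0.29 (adjusted p = 7.79e-09 and 9.48e-06, and 0.751 and 0.834 with an estimated correlation). Against untreated 1 alone the medians were -0.024 and 0.023, and against untreated 2 alone -0.81 and -0.60. These values are consistent with a difference between the untreated libraries, where the lists differed by 0.74 and 0.61.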
